A study of Homo sapiens with 4 samples.

How the data were processed

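RNA sequencing was done on cells that the labels describe as human Kupffer cells, the resident macrophages of the liver, from a purchased primary culture. The cells were grown in RPMI medium with 10% fetal bovine serum cleared of exosomes. Per the labels' protocols they received exosomes at 5 µg/mL every other day over 14 days in 6-well plates. There were 4 GEO samples, 1 per group: exosomes of normal pancreas, exosomes of PAN02 cells, PBS, and exosomes of BxPC-3 cells. PAN02 is a pancreatic adenocarcinoma line of the mouse and BxPC-3 one of human origin. RNA was extracted with a column kit and libraries followed the standard Illumina protocol, per the labels. The labels do not say whether poly(A) RNA was selected or whether the libraries kept strand.

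The authors deposited 2 tables, one with the normal pancreas and PAN02 exosome samples and one with the PBS and BxPC-3 exosome samples. Each table has 23710 rows of genes with raw counts, and the deposited counts stand in 3 numbered columns per sample. The authors' tables also give a log2 fold change, a p-value and an adjusted p per gene, per the file headers. Scaled values that stand under repeated column names in the deposited tables were not used here. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.11, HTSeq 0.6.1, edgeR 3.8.2 and the genome build hg19, with no role or order. The annotation release is not given in the sources used here. The reference at hand was GRCh38 with GENCODE release 29, another build, so no coordinates are printed, and it served only for gene names, transcript lengths and GC content.

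The labels name 1 sample per group and do not explain the numbers of the columns, so the 3 columns of a sample were summed and counted as 1 library. Columns held 49922515 to 62018714 counts, and the summed libraries held 160663934 (normal pancreas exosomes), 172243467 (PAN02 exosomes), 162198360 (PBS) and 159494916 (BxPC-3 exosomes). At these depths 0 counts allow a level of up to 0.0167 to 0.0194 CPM (counts scaled by the TMM-adjusted library total), taking a limit of 3 counts. Columns of 1 sample differed by more than counting noise. They can be runs, library preparations or separate cultures, which neither the labels nor this spread settle. In a chi-square test over genes with 30 or more counts, 55.6%, 51.2%, 42.8% and 50.2% of genes in the same order of samples had a p-value under 0.05. A spreadsheet had turned 28 gene symbols into dates in each table. The accessions in their rows restored 27 of them, and the last was left out. Older symbols are printed as in the tables, such as IL8 for CXCL8.

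Counts of each library were scaled with edgeR 4.0.16 (TMM, R 4.3.3), which gave factors of 1.12 and 0.896 in the first table and 1.00 and 0.996 in the second. Genes with 20 or more counts summed over the pair were kept. The log2 ratio is that of TMM-scaled CPM with a prior count of 2, PAN02 over normal pancreas exosomes and BxPC-3 exosomes over PBS. A gene is called higher or lower where the ratio was at least 2-fold (log2 ratio of 1 or more in size) and the exact 95% Clopper-Pearson interval of the ratio excluded 1. This interval covers counting error only. On the summed libraries, 1 per group, no test between treatments is possible and no p-value between treatments is given. The value after ± is the standard error of the log2 ratio over the 3 columns of each library, which measures the spread between columns, be it technical or that of separate cultures. Levels are written with the reference library (normal pancreas exosomes or PBS) first.

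Because the tables held several columns per library, an edgeR quasi-likelihood test over 3 against 3 columns with Benjamini-Hochberg adjustment at 0.05 was added after the data were seen. It compares the columns of 2 samples. It would be a test between treatments if the columns are separate cultures, and it is not read as one here because the labels do not say so. A joint fit of all 12 columns tested per gene whether the log2 ratios of the 2 comparisons differed, with the same limit.

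The groups, the size rule, its alternatives, 36 gene lists and the rule for named genes were fixed before the data were examined. The lists hold 837 entries, of which 823 have a row in both tables. A list is described by how many kept members were higher or lower and by its median log2 ratio, except the sterol synthesis list, for which the median alone is given. Lists with at least 5 kept members were set against 10000 random lists of the same size matched on mean expression in 20 bins. The central 95% of those medians describes these libraries and is no test of treatment. Named genes are the 8 highest and the 8 lowest log2 ratios with at least 100 summed counts in each comparison, up to 4 members of each list with the largest log2 ratio in size, and 5 genes per direction of the overlap. Clone names, non-coding and pseudogene names, immune receptor segments, sex-linked markers and genes that follow a donor's genotype were left out. TGFB1, FN1, MIF, CD74, CD44, TIMP1, CD68 and CD163 are always given. Counting could not be checked for reads shared between paralogs or overlapping genes, which holds for the keratin, metallothionein, histone, ribosomal protein and CXCL gene families named here.

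Alternatives were DESeq2 1.42.0 size factors or total counts in place of TMM, prior counts of 0.5 and 10, no filter or 100 counts, a log2 ratio of 2, and an interval beyond 1.5-fold. Leaving out each count column was added after the data were seen. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 computed the list statistics and matplotlib 3.10.9 drew the figures.

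Both procedures were tested on simulated data with 50 changed genes for each fold size. Counts for the size rule were drawn with counting noise only, and those for the quasi-likelihood test with added spread between columns. False calls of the size rule in this simulation therefore cover counting error alone, and not a difference between libraries of 1 treatment. For the PAN02 comparison (16267 genes) the size rule recovered 98% of 3-fold, 96% of 4-fold and 94% of 8-fold changes and 0% of 1.5-fold changes, which lie under its 2-fold limit, with 31 false calls among 16067 unchanged genes. For the BxPC-3 comparison (16244 genes) these shares were 96%, 98%, 98% and 0%, with 33 false calls among 16044. In the same order of folds the quasi-likelihood test recovered 94%, 92%, 94% and 84% in the first and 92%, 96%, 98% and 82% in the second, with 13 and 7 false calls. Of 100 random lists of 25 genes per comparison, 5% (PAN02) and 6% (BxPC-3) fell outside the central 95% without a shift, and 100% lay above it after a shift of 1 on the log2 scale.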

Results

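Transcript levels were measured by RNA sequencing in cells described by the labels as human Kupffer cells and cultured for 14 days with exosomes or with PBS. The study asked how exosomes of pancreatic cancer cells act on the liver's resident macrophages, a step that its title ties to the niche in which metastases later grow. There were 4 libraries, 1 for each treatment and each the sum of 3 count columns that the labels do not explain, with 159494916 to 172243467 counts each. PAN02 exosomes stood against exosomes of normal pancreas in one table, and BxPC-3 exosomes against PBS in the other. The second pair therefore cannot separate an effect of BxPC-3 exosomes from one of any exosomes.

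All 4 libraries were rich in transcripts of collagen-producing mesenchymal cells and poor in those of macrophages. FN1 (fibronectin), COL1A1, COL1A2, COL3A1 (fibrillar collagens) and IGFBP5, a secreted binding protein of insulin-like growth factors, were among the most abundant transcripts. FN1 took 0.881% of all counts with normal pancreas exosomes, 3.52% with PAN02 exosomes, 1.83% with PBS and 1.96% with BxPC-3 exosomes. The 24 stellate cell and fibroblast genes had median levels of 293 (normal pancreas exosomes), 1101 (PAN02 exosomes), 522 (PBS) and 567 CPM (BxPC-3 exosomes). For the 30 Kupffer cell and macrophage genes the medians were 0.0586, 0.0227, 0.442 and 0.595 CPM in the same order. Of the macrophage genes, CD68, a lysosomal protein that is not restricted to macrophages, stood at 149.7, 80.7, 47.3 and 70.5 CPM. CD163, the haemoglobin scavenger receptor, stood at 0.0446, 0.0130, 0.934 and 1.01 CPM. PTPRC, the pan-leukocyte gene, reached at most 0.403 CPM, and MARCO and VSIG4, receptors of Kupffer cells, were listed at 0 in both libraries of the first table and at 0.0369 to 0.120 CPM in the second. PTPRC, MARCO and VSIG4 were chosen after their values were seen.

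**Figure D1:**
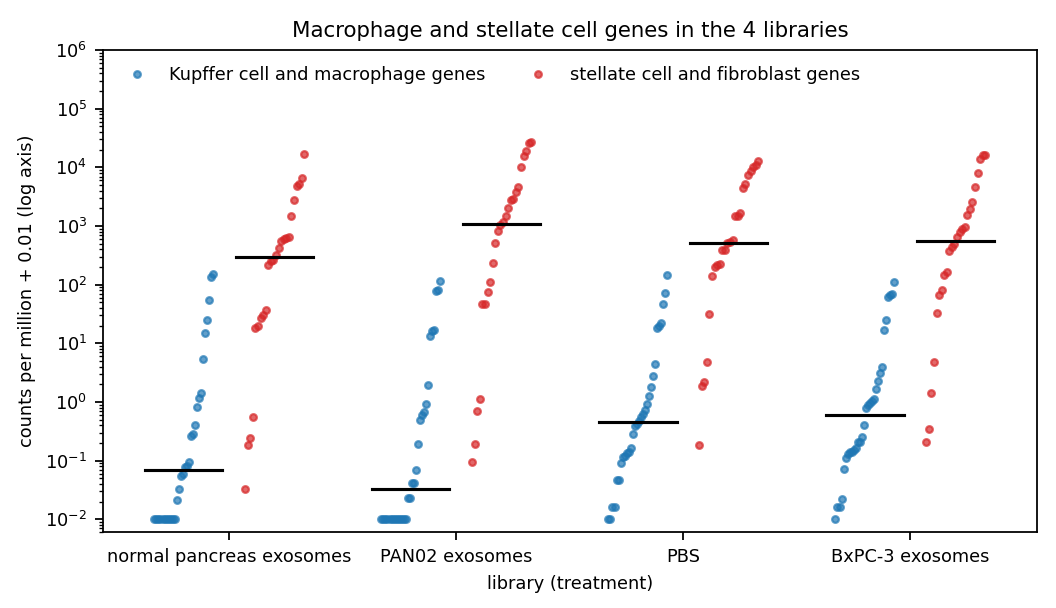
Levels of the 30 Kupffer cell and macrophage genes (blue) and the 24 stellate cell and fibroblast genes (red) in each library, as CPM plus 0.01 on a log axis. Each point is a gene and each black line the median of its list. The red medians, 293 to 1101 CPM, lie above the blue ones, 0.0227 to 0.595 CPM, in all 4 libraries, and the 2 tables were scaled separately.

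Transcripts of the other cell types considered were low. Median levels were at most 0.0252 CPM for 25 hepatocyte genes and 0.574 CPM for 18 endothelial genes. For 17 T and natural killer cell, 12 B and plasma cell, 13 neutrophil, 16 dendritic cell and 22 pancreatic acinar and islet genes the highest medians were 0.0223, 0.0279, 0.0307, 0.00922 and 0.00629 CPM. Among 20 biliary and other epithelial genes, with medians of 0.153 to 0.491 CPM, KRT18 was the exception, with 32.1 CPM (normal pancreas exosomes), 352 (PAN02 exosomes), 1060.3 (PBS) and 222 (BxPC-3 exosomes). Levels of different tables were scaled separately and carry no test.

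MIF, the cytokine called macrophage migration inhibitory factor, was listed at 0 in every column. In the summed libraries this allows at most 0.0167 to 0.0194 CPM. Since MIF transcripts are found in most cells, a count of 0 describes the tables and not necessarily the cells. CD74, which encodes the MIF receptor chain, stood at 0.530 and 0.402 CPM in the first table and at 6.41 and 8.01 CPM in the second. Its log2 ratios of -0.39 ± 0.06 and 0.32 ± 0.18 did not pass the size rule.

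With PAN02 exosomes in place of normal pancreas exosomes, transcripts of the matrix, of stellate cells and fibroblasts and of the interferon response stood higher, and transcripts of chemokines and inflammatory cytokines stood lower. Of 16266 genes kept, 1157 were higher and 591 lower. FN1 stood at 7891 CPM with normal pancreas exosomes and at 39266 CPM with PAN02 exosomes, a log2 ratio of 2.31 ± 0.16. IL8, the neutrophil chemoattractant, went the other way, at 12363 and 383 CPM, a log2 ratio of -5.01 ± 0.25. TGFB1, which encodes the fibrogenic cytokine TGF-beta 1, stood at 107 and 124 CPM; its log2 ratio of 0.22 ± 0.11 did not pass the size rule and became -0.10 with total counts as the scale.

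Among the 30 extracellular matrix genes, 20 were higher and 0 lower, with a median log2 ratio of 1.15 (central 95% of random lists -0.02 to 0.36). ELN, which encodes elastin, had 9.25 and 77.9 CPM, log2 ratio 3.07 ± 0.39, COL1A1 4784 and 27436 CPM, log2 ratio 2.52 ± 0.26, and COL4A1, a chain of basement membrane collagen, 1136 and 6424 CPM, log2 ratio 2.50 ± 0.24. Of 23 stellate cell and fibroblast genes kept, 18 were higher and 0 lower (median 1.70, random lists -0.09 to 0.34). They included the contractile genes ACTA2 (249.8 and 4614 CPM, log2 ratio 4.21 ± 0.40), a marker of activated stellate cells, CNN1 (18.5 and 231 CPM, log2 ratio 3.64 ± 0.26) and TAGLN (431 and 2817 CPM, log2 ratio 2.71 ± 0.24). With all 4 libraries on 1 scale, ACTA2, CNN1 and TAGLN were each lowest with normal pancreas exosomes and highest with PBS. COL1A1 and other collagens stand in both the matrix and the stellate list. The TGF-beta response list had 4 of 22 members higher and 1 lower (median 0.38, random lists -0.11 to 0.25), with CTGF (562 and 2193 CPM, log2 ratio 1.96 ± 0.20), CDKN2B (31.5 and 109.9 CPM), LTBP2 (1.74 ± 0.16) and BAMBI (1.55 ± 0.15) higher. The lower gene was ID1 (-1.30 ± 0.22). Of 27 secreted fibrosis factors, 8 were higher and 4 lower (median 0.42, random lists -0.11 to 0.25). IGF1 (2.48 and 13.3 CPM, log2 ratio 2.42 ± 0.58) and THBS1 (3223 and 14389 CPM, log2 ratio 2.16 ± 0.22), which can activate latent TGF-beta, were higher, while the epidermal growth factor receptor ligands TGFA (6.21 and 0.654 CPM, log2 ratio -3.22 ± 0.15) and HBEGF (29.3 and 7.20 CPM, log2 ratio -2.02 ± 0.15) were lower, as were VEGFA (-1.27 ± 0.15) and GDF15 (-1.73 ± 0.23).

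Of 18 chemokines kept, 11 were lower and 2 higher with PAN02 exosomes (median -1.71, random lists -0.21 to 0.28). With all 4 libraries on 1 scale the normal pancreas exosome library was the highest for 8 of these 11. The lowest ratios were those of the neutrophil-attracting CXCL3 (142 and 4.35 CPM, log2 ratio -5.02 ± 0.45), IL8, CXCL5 (88.5 and 3.45 CPM, log2 ratio -4.68 ± 0.56) and CXCL1 (1009 and 46.7 CPM, log2 ratio -4.43 ± 0.21). CXCL12 (1.08 ± 0.06) and CX3CL1 (1.28 ± 0.24) were the higher ones. Among 26 inflammatory cytokines and targets of NF-kappaB, 13 were lower and 1 higher (median -0.99, random lists -0.15 to 0.24). CSF2, which encodes GM-CSF, had 19.6 and 0.285 CPM, log2 ratio -6.04 ± 0.49, IL1B 1444 and 58.8 CPM, log2 ratio -4.62 ± 0.21, and PTGS2, the inducible cyclooxygenase, 1453 and 119 CPM, log2 ratio -3.61 ± 0.20. CSF3 also stood lower, at 0.792 and 0.0259 CPM, and the higher gene was CFB, a complement factor. In the list of 24 matrix proteases, their inhibitors and the urokinase receptor, MMP3 (949.6 and 50.6 CPM, log2 ratio -4.23 ± 0.47), MMP10 (48.6 and 3.40 CPM, log2 ratio -3.84 ± 0.30), MMP1 (10709 and 883 CPM, log2 ratio -3.60 ± 0.29) and the plasminogen activator PLAU (88.4 and 10.6 CPM, log2 ratio -3.06 ± 0.19) led 8 lower genes, beside MMP2 (1.08 ± 0.11) and the inhibitor TIMP3 (1.45 ± 0.19), which were higher. The median of this list lay inside the random range (median -0.03, random lists -0.10 to 0.28). TIMP1, an inhibitor of these proteases, stood at 3157 and 3344 CPM, and its log2 ratio of 0.08 ± 0.07 became -0.23 with total counts as the scale.

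Interferon-stimulated genes stood higher in 26 of 34 cases and lower in 0 (median 1.68, random lists -0.13 to 0.15). The antiviral GTPases MX2 (1.13 and 28.5 CPM, log2 ratio 4.64 ± 0.61) and MX1 (7.60 and 119.8 CPM, log2 ratio 3.98 ± 0.52) and the RNA sensor OAS1 (1.94 and 26.5 CPM, log2 ratio 3.76 ± 0.53) led, followed by IFI44L (6.63 and 83.9 CPM, log2 ratio 3.66 ± 0.53). Complement and coagulation genes had 7 members higher and 3 lower of 18 (median 0.45, random lists -0.20 to 0.28), with A2M (4.91 and 35.9 CPM, log2 ratio 2.87 ± 0.37) and the complement factors CFB (15.1 and 62.1 CPM, log2 ratio 2.04 ± 0.24) and C2 (0.926 and 3.45 CPM, log2 ratio 1.88 ± 0.10) higher and THBD, thrombomodulin (34.1 and 8.48 CPM, log2 ratio -2.01 ± 0.23), C3AR1 (-1.08 ± 0.61) and CFP (-1.40 ± 0.58) lower. Of 14 biliary and other epithelial genes, 9 were higher and 0 lower (median 1.10, random lists -0.29 to 0.29). They were led by the keratins KRT18 (32.1 and 352 CPM, log2 ratio 3.45 ± 0.13), KRT7 (8.23 and 57.2 CPM, log2 ratio 2.80 ± 0.32) and KRT19 (0.993 and 5.93 CPM, log2 ratio 2.56 ± 0.22), and CDH1, E-cadherin, stood at 0.0781 and 0.408 CPM.

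The 13 macrophage genes kept showed no shift as a list: 2 were higher and 0 lower (median 0.18, random lists -0.27 to 0.31; -0.14 with total counts as the scale). CD14, the lipopolysaccharide co-receptor (5.31 and 13.3 CPM, log2 ratio 1.32 ± 0.10), and LYVE1, a hyaluronan receptor (0.279 and 0.654 CPM, log2 ratio 1.20 ± 0.14), were higher, and CD68 had a log2 ratio of -0.89 ± 0.14, short of the size rule. In the list of MIF and its receptors 5 of 7 genes were kept (median -0.39, random lists -0.60 to 0.80). CXCR4 (0.139 and 0.00648 CPM, log2 ratio -3.04, counting interval -9.79 to -1.82, from 1 count in the PAN02 exosome library) and CD44 (1473 and 735 CPM, barely past the 2-fold limit), the co-receptor of CD74, were lower, and CXCR7 (0.669 and 2.57 CPM, log2 ratio 1.92 ± 0.19) was higher.

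Of the genes in these lists, ID1, GDF15, CXCL12, CX3CL1, MMP2, TIMP3, C3AR1 and CFP were named after their values were seen, to complete small counts. The highest log2 ratios of single genes belonged to ADH1B, an alcohol dehydrogenase (0.323 and 23.04 CPM, log2 ratio 6.10 ± 0.71), the smooth muscle myosin MYH11 (3.56 and 183 CPM, log2 ratio 5.67 ± 0.65), the natriuretic peptide gene NPPB (0.379 and 16.9 CPM, log2 ratio 5.43 ± 0.23), the cardiac troponin TNNT2 (0.0390 and 1.90 CPM, log2 ratio 5.23 ± 0.33) and SYTL5 (0.0279 and 1.26 CPM). ACTC1, cardiac actin (0.0725 and 2.49 CPM), B3GALT2 (0.312 and 9.08 CPM) and ASPN, asporin (2.72 and 74.4 CPM), completed the 8. The lowest were CSF2, the cytokine IL24 (367 and 9.32 CPM, log2 ratio -5.30 ± 0.48), the epithelial transcription factor EHF (3.76 and 0.0972 CPM, log2 ratio -5.11 ± 0.56), CXCL3, IL8, TMEM132B (36.1 and 1.15 CPM, log2 ratio -4.95 ± 0.22), the immediate early gene ARC (3.61 and 0.110 CPM, log2 ratio -4.89 ± 0.68) and CXCL5.

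The size rule compares 2 summed libraries and uses no replicates, and whether the 3 columns of each are separate cultures is not stated in the labels. Of the 1748 genes past it, 1660 also passed the edgeR quasi-likelihood test over columns (3982 genes higher and 3796 lower in all), whose spread can be technical or that of cultures. Scaling by total counts in place of TMM moved the median of all genes by -0.32, which is the log2 ratio of the 2 TMM factors. It changed the share of higher genes from 66.2% to 40.3% of the genes past the size rule, and from 51.2% to 19.2% of those past the test over columns. Replication histones (6 of 13 lower, median -0.996, random lists -0.36 to 0.34), which can follow RNA quality or selection, also lay below random lists in this comparison. So did the list of immediate early and dissociation stress genes (1 of 22 higher and 6 lower, median -0.31, random lists -0.15 to 0.18).

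**Figure D2:**
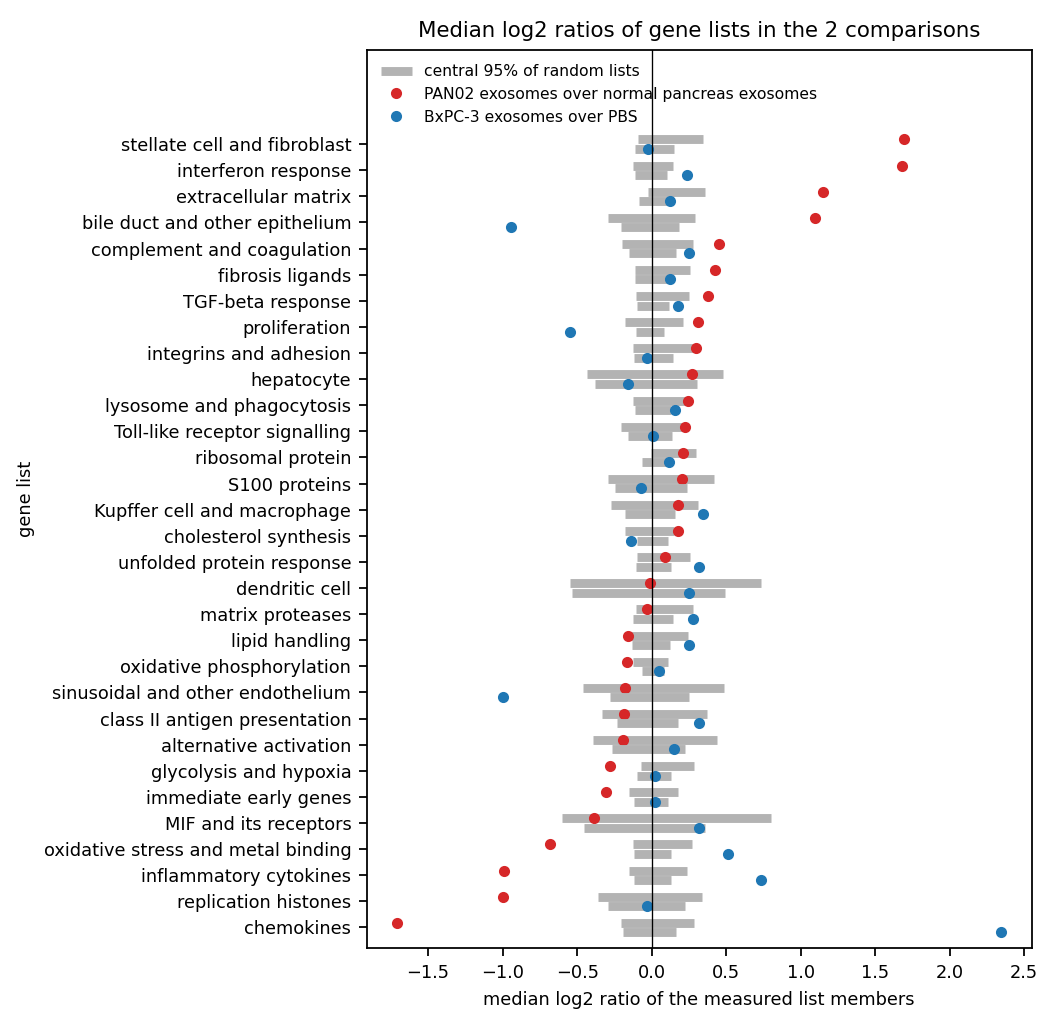
Median log2 ratio of each gene list (dots) for PAN02 over normal pancreas exosomes (red) and BxPC-3 exosomes over PBS (blue), with grey bars for the central 95% of 10000 random lists of matched expression. Chemokines lie at -1.71 and 2.35 in the 2 comparisons, and the extracellular matrix list at 1.15 and 0.13. With total counts as the scale, the red dots of 10 lists between 0 and 0.32 move below 0.

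With BxPC-3 exosomes in place of PBS, chemokine and inflammatory transcripts stood higher. Epithelial markers and some endothelial markers of low level stood lower, and none of the listed matrix transcripts reached the 2-fold limit. Of 16243 genes kept, 332 were higher and 464 lower. IL8 stood at 16.004 CPM with PBS and at 414 CPM with BxPC-3 exosomes, a log2 ratio of 4.69 ± 0.42. FN1 stood at 18262 and 19630 CPM, with a log2 ratio of 0.10 ± 0.09 that did not pass the size rule. TGFB1 (62.9 and 68.4 CPM, log2 ratio 0.12 ± 0.15) did not pass it either.

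Of 19 chemokines kept, 14 were higher and 0 lower (median 2.35, random lists -0.19 to 0.16). Besides IL8 they included CXCL3 (0.627 and 13.3 CPM, log2 ratio 4.38 ± 0.43), the monocyte-attracting CCL7 (2.49 and 39.1 CPM, log2 ratio 3.96 ± 0.29) and CXCL1 (10.7 and 127 CPM, log2 ratio 3.56 ± 0.58). Among 26 inflammatory cytokines, 10 were higher and 0 lower (median 0.73, random lists -0.12 to 0.13), with CSF2 (0.190 and 2.04 CPM, log2 ratio 3.34 ± 0.31), CSF3 (0.0123 and 0.182 CPM, log2 ratio 2.98, counting interval 1.91 to 7.005), IL1B (49.4 and 254 CPM, log2 ratio 2.36 ± 0.38) and PTGS2 (105 and 506 CPM, log2 ratio 2.26 ± 0.23) showing the widest ratios. The first of these CSF3 levels rests on 2 counts. In the list of 25 matrix proteases and inhibitors 5 genes were higher and 0 lower (median 0.28, random lists -0.13 to 0.14): MMP9 (0.0676 and 1.38 CPM, log2 ratio 4.13 ± 0.39), MMP12 (0.756 and 2.26 CPM, log2 ratio 1.56 ± 0.24), MMP10 (1.08 and 2.68 CPM, log2 ratio 1.31 ± 0.21), and the cathepsins CTSS (4.12 and 10.2 CPM, log2 ratio 1.31 ± 0.16) and CTSL1 (1.08 ± 0.14). Of the genes that bind metals or answer oxidative stress, 3 of 22 were higher and 0 lower (median 0.52, random lists -0.12 to 0.13): HMOX1, heme oxygenase (18.1 and 62.3 CPM, log2 ratio 1.79 ± 0.22), the ferritin chain FTH1 (2298 and 5461 CPM, log2 ratio 1.25 ± 0.08) and the cystine transporter SLC7A11 (122 and 289 CPM, log2 ratio 1.25 ± 0.13).

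Of the 30 matrix genes 0 passed the size rule, and their median was 0.13 (random lists -0.08 to 0.14). After removal of the trend on GC content and transcript length the median was 0.22, above random lists (-0.07 to 0.14). The widest ratios were those of COL3A1 (8651 and 16382 CPM, log2 ratio 0.92 ± 0.10) and TNC, tenascin (120.5 and 213 CPM, log2 ratio 0.82 ± 0.11). In the stellate cell and fibroblast list 5 of 24 genes were lower and 0 higher, with a median inside the random range (median -0.02, random lists -0.11 to 0.15). The lower genes were the intermediate filament DES (1.83 and 0.340 CPM, log2 ratio -2.39 ± 0.51), the pericyte gene RGS5 (228 and 65.6 CPM, log2 ratio -1.79 ± 0.12), CNN1 (216 and 80.9 CPM, log2 ratio -1.41 ± 0.38), ACTA2 (5153 and 1992 CPM, log2 ratio -1.37 ± 0.50) and IGFBP5 (-1.26 ± 0.14). Of 22 TGF-beta response genes 1 was lower, CTGF (1630 and 810.4 CPM, log2 ratio -1.01 ± 0.34), and 0 were higher, although the list median lay above random lists (median 0.17, random lists -0.10 to 0.12). Secreted fibrosis factors had 4 of 27 members higher and 5 lower, with a median barely above random lists (median 0.123, random lists -0.109 to 0.119). EDN1, endothelin (19.6 and 5.99 CPM, log2 ratio -1.71 ± 0.29), TGFB3 (34.0 and 12.5 CPM, log2 ratio -1.44 ± 0.22), PDGFB (12.9 and 5.06 CPM, log2 ratio -1.35 ± 0.15), TGFA (-1.02 ± 0.32) and CTGF were lower, and IGF1 (1.63 and 4.01 CPM, log2 ratio 1.29 ± 0.14), HGF (1.28 ± 0.20), GDF15 (1.25 ± 0.20) and SPP1, osteopontin (1.03 ± 0.20), were higher. CTSL1, IGFBP5, TGFA, HGF, GDF15 and SPP1 were named after their values were seen, to complete these counts.

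Biliary and other epithelial genes were lower in 6 of 14 cases and higher in 0 (median -0.94, random lists -0.21 to 0.18), led by KRT18 (1060 and 222 CPM, log2 ratio -2.26 ± 0.28) and KRT7 (58.5 and 19.04 CPM, log2 ratio -1.62 ± 0.35). The endothelial list had 7 of 14 members lower and 0 higher (median -0.997, random lists -0.28 to 0.25). The lower ones included CRHBP (0.547 and 0.0440 CPM, log2 ratio -3.31 ± 0.47), OIT3 (0.252 and 0.0692 CPM) and FCN3 (0.565 and 0.195 CPM). TEK, the most abundant member (47.4 and 49.0 CPM), PECAM1 (0.66 and 0.68 CPM) and VWF (0.77 and 0.79 CPM) did not pass the size rule. TEK, PECAM1 and VWF were named after their values were seen. The macrophage list had 2 of 25 members higher and 1 lower, and its median lay above the random range (median 0.35, random lists -0.18 to 0.15). HMOX1 and MARCO (0.0369 and 0.101 CPM, log2 ratio 1.20 ± 0.37, from only 6 and 16 counts) were higher and LYVE1 (0.412 and 0.132 CPM, log2 ratio -1.55 ± 0.53) was lower. CD68 (47.3 and 70.5 CPM, log2 ratio 0.57 ± 0.11), CD163 (0.934 and 1.01 CPM, log2 ratio 0.12 ± 0.45), CD44 (454 and 621 CPM, log2 ratio 0.45 ± 0.14) and TIMP1 (2484 and 3630 CPM, log2 ratio 0.55 ± 0.18) did not pass the size rule. In the list of MIF and its receptors 0 of 5 kept genes passed (median 0.32, random lists -0.45 to 0.36). Interferon-stimulated genes had 3 of 35 members higher and 0 lower (median 0.24, random lists -0.11 to 0.10): IFI44L (0.332 and 1.23 CPM, log2 ratio 1.85 ± 0.52), GBP5 (0.326 and 0.717 CPM, log2 ratio 1.11 ± 0.26) and OASL (0.0860 and 0.195 CPM). Of 22 complement and coagulation genes, C3 (212 and 531 CPM, log2 ratio 1.33 ± 0.14) was higher and A2M (62.9 and 18.8 CPM, log2 ratio -1.74 ± 0.42) lower (median 0.25, random lists -0.15 to 0.16).

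Besides IL8, CXCL3, CCL7, CXCL1, MMP9 and CSF2, the 8 highest log2 ratios included CCL20 (0.516 and 5.73 CPM, log2 ratio 3.44 ± 0.09) and CXCL2 (1.19 and 12.9 CPM, log2 ratio 3.42 ± 0.28). The 8 lowest were those of the sodium-coupled transporter SLC5A12 (17.9 and 0.900 CPM, log2 ratio -4.30 ± 0.94), the muscle protein genes CSRP3 (1.27 and 0.0566 CPM, log2 ratio -4.22 ± 0.26) and XIRP1 (1.20 and 0.132 CPM), the secreted ligand WNT7A (0.657 and 0.0315 CPM), the proteoglycan ACAN (1.68 and 0.120 CPM, log2 ratio -3.68 ± 0.37), the apelin receptor APLNR (0.670 and 0.0566 CPM), the oxytocin receptor OXTR (251 and 34.4 CPM, log2 ratio -2.86 ± 0.47) and TNNT2 (29.1 and 3.99 CPM, log2 ratio -2.86 ± 0.89).

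This comparison too sets 1 summed library against another, with the same limit on what the columns are. Of its 796 genes past the size rule, 662 also passed the edgeR quasi-likelihood test over columns, which 2288 genes passed as higher and 2420 as lower. Without the second PBS column that total of 4708 became 2937. Scaling by total counts moved the median of all genes by -0.01.

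The log2 ratios of the 2 comparisons tended to go in opposite directions. Over 15735 genes kept in both tables Pearson's r was -0.35 and Spearman's rho -0.22, across genes, which are not independent replicates. Genes higher with PAN02 and lower with BxPC-3 exosomes numbered 182, where independent lists would share 27.0, and 109 genes went the other way, where 9.25 would be shared. The first kind included ACAN (log2 ratios 4.45, counting interval 3.61 to 7.50 from 3 counts with normal pancreas exosomes, and -3.68 ± 0.37), OXTR (4.25 ± 0.39 and -2.86 ± 0.47), TNNT2 (5.23 ± 0.33 and -2.86 ± 0.89), ACTC1 (4.89 ± 0.36 and -2.60 ± 0.41) and the cytolinker EPPK1 (3.42 ± 0.36 and -2.48 ± 0.36). The second kind included IL8, CXCL3, CXCL1, CXCL2 (-3.51 ± 0.39 and 3.42 ± 0.28) and CSF2. Genes higher in both comparisons numbered 35, where 20.4 would be shared, and those lower in both 19, where 12.2 would be. MEOX1, CCL11, IFI44L, MYH15 and TRIL were higher in both, with log2 ratios of 2.66 ± 0.43, 1.95 ± 0.62, 3.66 ± 0.53, 2.20 ± 0.19 and 2.44 ± 0.30 for PAN02 exosomes and of 2.86 ± 0.27, 1.90 ± 0.33, 1.85 ± 0.52, 1.82 ± 0.46 and 1.64 ± 0.39 for BxPC-3 exosomes. XIRP1, MYPN, XDH, CORO1A and BTBD11 were lower in both.

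A joint edgeR quasi-likelihood fit over all 12 columns tested the difference of the 2 log2 ratios itself. It passed for 7352 of 15735 genes, 2273 of them with a difference of at least 2-fold. The 2 comparisons share no library and no kind of control, and the difference rests on the spread between columns.

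**Figure D3:**
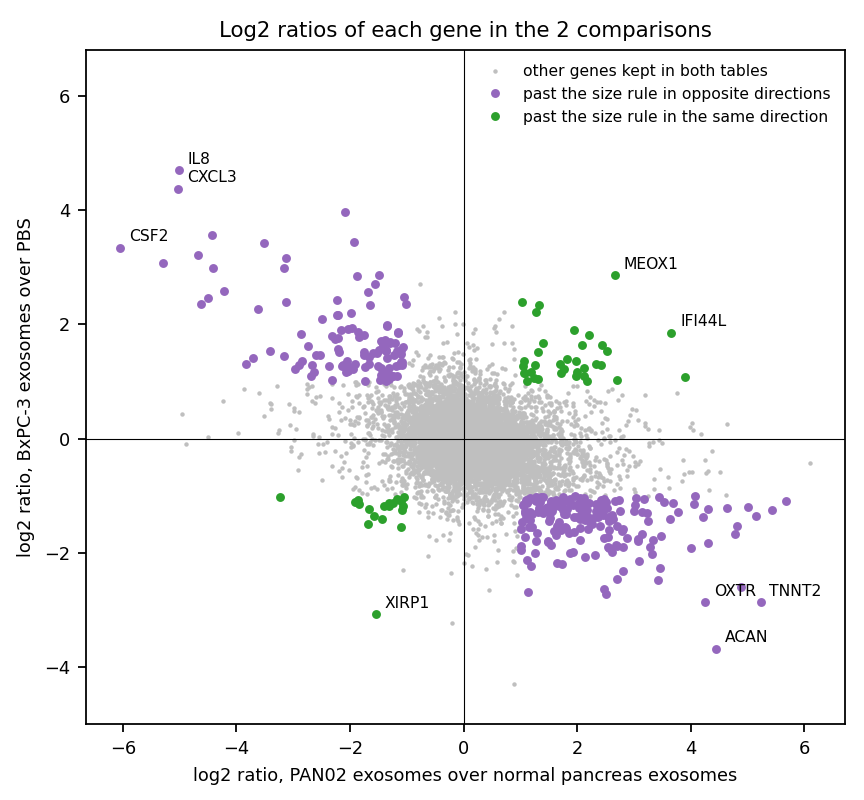
Log2 ratio of each gene for PAN02 over normal pancreas exosomes (horizontal axis) against that for BxPC-3 exosomes over PBS (vertical axis). Grey points are other genes kept in both tables, purple ones the 291 genes past the size rule in opposite directions and green ones the 54 past it in the same direction.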

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

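Tests of counting noise and of exchanged labels were chosen after the correlation had been seen, and so was the joint fit over columns.

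For 6 gene lists the median log2 ratio lay on opposite sides of the random lists in the 2 comparisons. The chemokine median in the PAN02 comparison minus that in the BxPC-3 comparison was -4.05, and 13 of 17 members differed in the joint quasi-likelihood fit over columns. Inflammatory cytokines differed by -1.72 (19 of 26 members) and genes of oxidative stress and metal binding by -1.19 (17 of 22). Biliary and other epithelial genes differed by 2.04 (8 of 13 members), cell cycle genes by 0.855 (15 of 30) and sterol synthesis genes by 0.314 (16 of 23). Over all genes 7352 of 15735 differed in that fit, so the share among cell cycle genes is close to that of all genes. The PAN02 medians of the last 2 lists were 0.31 and 0.18 and became -0.0059 and -0.14 with total counts as the scale, by a shift that is common to all genes and so moves the random lists too.

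The 291 genes that passed the size rule in opposite directions stood out in the same way, with a Pearson r of -0.35 over all genes kept in both tables. Over 10618 genes with 1000 or more counts in both tables r was -0.421, which decides nothing about counting noise, since the tables share no library and independent noise pulls r toward 0. GC content and transcript length are argued against by an r of -0.346 after their trend was removed from each comparison. An exchange of the 2 labels within 1 table would by arithmetic give an r of 0.348, and no value in the tables decides it, so it cannot be told apart from a difference between treatments. The controls also differ, normal pancreas exosomes in one table and PBS in the other. An effect of the normal exosomes themselves stays open, as does a true difference between PAN02 and BxPC-3 exosomes, and neither was tested. The tables also differed in level. On 1 scale cell cycle medians were 2.40 (normal pancreas exosomes), 2.98 (PAN02 exosomes), 18.4 (PBS) and 11.9 CPM (BxPC-3 exosomes), and 28 of 30 genes were highest with PBS. A difference between the cells or the handling of the 2 tables is confounded with the comparison and was not tested.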

How the results depend on the processing

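Leaving out count columns and each setting of the test over columns were chosen after the data were seen. A list median counted as moved where it changed by 0.1 or more. Under the other scalings, prior counts and filters the counts of genes past the size rule stayed within 1.5 times 1748 and 796, and a log2 ratio of 2 or more gave 453 and 110 by construction. Leaving out 1 column gave 1595 to 1852 and 706 to 889. The test over columns gave 6661 to 7896 genes (7778 with all columns) and 2937 to 4412 (4708 with all) without 1 column, 7235 and 4291 by a DESeq2 Wald test, and 7742 and 4116 by the adjusted p in the authors' deposited tables. Lists outside the random range numbered 16 (16 to 20 without 1 column) and 17 (16 to 18). With total counts as the scale the PAN02 medians of cell cycle and sterol synthesis genes reversed to -0.0059 and -0.14, as a shift of -0.32 in all genes entails. That scale also took the test over columns to 10683 and 4435 genes, of which 19.2% of the first were higher against 51.2%. Single genes near 0 also changed sign with that scale, among them TGFB1 (0.22 to -0.10) and TIMP1 (0.08 to -0.23). Of the other alternative list medians, 305 of the PAN02 comparison stayed and 89 moved, and 320 and 52 of the BxPC-3 comparison.

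The correlation of the 2 comparisons kept its sign. It was -0.26 without a filter and -0.39 with 100 counts, where fewer noisy genes enter, and Spearman's rho was then -0.24. Without 1 column it ranged from -0.39 to -0.28; the cause was not tested. The 54 calls in the same direction became 35 with a prior count of 10 and 33 with 100 counts, where fewer genes pass, and 43 to 55 without 1 column. The 291 opposite calls became 233 to 372 without 1 column.

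Same-numbered columns did not pair: their deviations correlated by -0.29, 0.06 and 0.08 in the first table and -0.14, -0.35 and 0.38 in the second. Differently numbered columns of the second table ranged from -0.499 (PBS column 1 with BxPC-3 column 3) to 0.525 (PBS column 1 with BxPC-3 column 2). With the column number as a replicate block the test over columns gave 7432 and 3941 genes. A pairing of the columns in another order was not tested. Genes under 20 counts per pair have no ratio here, and the filter at 100 counts leaves out named genes below it.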

Other observations

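Tests of cell type levels, of the library that stands apart and of the matrix share against a fixed bound were chosen after the levels had been seen, and the test over columns behind the splits was added after the data were seen.

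Metabolic and stress transcripts also moved between the libraries. With PAN02 exosomes 7 of 22 genes of oxidative stress and metal binding were lower and 0 higher (median -0.68, random lists -0.12 to 0.27), led by the metallothioneins MT1G (1.47 and 0.175 CPM, log2 ratio -2.99 ± 0.32) and MT2A (1017 and 234 CPM, log2 ratio -2.12 ± 0.15). Glycolysis and hypoxia genes had 5 of 29 members lower and 0 higher (median -0.28, random lists -0.07 to 0.29), among them ENO2 (184 and 65.9 CPM, log2 ratio -1.48 ± 0.11), VEGFA (728 and 302 CPM, log2 ratio -1.27 ± 0.15) and ADM (-1.25 ± 0.17). Respiratory chain subunits had 0 of 34 past the size rule, with a slightly lower median (median -0.17, random lists -0.12 to 0.11). Lipid handling genes had 4 of 21 lower (median -0.16, random lists -0.17 to 0.24): PDK4 (52.6 and 11.2 CPM, log2 ratio -2.23 ± 0.14), the lipid droplet protein PLIN2 (911 and 349.6 CPM, log2 ratio -1.38 ± 0.11), ABCG1 (-1.29 ± 0.17) and ANGPTL4 (-1.08 ± 0.14). With BxPC-3 exosomes 4 of 22 were higher (median 0.25, random lists -0.13 to 0.12): PDK4 (2.17 and 11.7 CPM, log2 ratio 2.42 ± 0.14), PLIN2 (213 and 705 CPM, log2 ratio 1.73 ± 0.10), ANGPTL4 (1.29 ± 0.21) and PLTP (1.04 ± 0.08). Of 29 glycolysis and hypoxia genes 0 passed there (median 0.03, random lists -0.10 to 0.13), and of 34 respiratory chain subunits 0 (median 0.05, random lists -0.07 to 0.08).

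Cell cycle genes had 3 of 30 members higher and 1 lower with PAN02 exosomes (median 0.31, random lists -0.18 to 0.21; -0.0059 with total counts as the scale): CCNB2 (0.407 and 0.998 CPM, log2 ratio 1.27 ± 0.35), MKI67 (1.29 and 2.97 CPM, log2 ratio 1.19 ± 0.46) and KIF20A (1.06 ± 0.48) were higher and AURKA (-1.11 ± 0.11) was lower. With BxPC-3 exosomes 2 of 30 were lower and 0 higher (median -0.55, random lists -0.11 to 0.08): CDC20 (21.4 and 9.54 CPM, log2 ratio -1.17 ± 0.46) and CCNE2 (-1.02 ± 0.24). The 23 sterol synthesis genes were scored as a list with PAN02 exosomes (median 0.18, random lists -0.18 to 0.15; -0.14 with total counts) and with BxPC-3 exosomes (median -0.14, random lists -0.10 to 0.11). The unfolded protein and amino acid response list had 3 of 23 higher and 2 lower with PAN02 exosomes (median 0.09, random lists -0.10 to 0.26, and -0.23 with total counts), the serine synthesis genes PHGDH (1.45 ± 0.11) and PSAT1 (1.43 ± 0.08) with ASNS (1.26 ± 0.09) against ATF3 (-1.60 ± 0.27) and PPP1R15A (-1.55 ± 0.20). With BxPC-3 exosomes 0 of 23 passed, and the median lay above random lists (median 0.32, random lists -0.10 to 0.13). Immediate early genes had 1 of 22 higher, EGR2 (1.32 ± 0.21), and 6 lower with PAN02 exosomes (median -0.31, random lists -0.15 to 0.18), among them FOSB (-1.93 ± 0.27). With BxPC-3 exosomes EGR2 (2.35 ± 0.37) was higher and DUSP1 (-1.25 ± 0.19) and EGR1 (-1.08 ± 0.17) were lower (median 0.02, random lists -0.12 to 0.11).

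Over all kept genes 10.7% passed the size rule with PAN02 exosomes and 4.90% with BxPC-3 exosomes. Lysosome and phagocytosis genes had 1 of 27 higher, GAS6 (1.29 ± 0.10), and 2 lower, ATP6V0D2 (1.10 and 0.104 CPM, log2 ratio -3.27 ± 0.34) and FCGR1A (-1.57 ± 0.42), with PAN02 exosomes (median 0.24, random lists -0.13 to 0.25, and -0.08 with total counts). With BxPC-3 exosomes GPNMB (81.4 and 168 CPM, log2 ratio 1.04 ± 0.19) and FCGR2B (0.0799 and 0.252 CPM) of 29 were higher (median 0.16, random lists -0.11 to 0.13). Toll-like receptor genes had TLR3 (1.58 ± 0.26), CD14 and TLR7 (1.12 ± 0.07) of 19 higher with PAN02 exosomes (median 0.23, random lists -0.21 to 0.23, and -0.08 with total counts) and 0 of 19 past the rule with BxPC-3 exosomes (median 0.01, random lists -0.16 to 0.14). Class II antigen presentation had CTSS (-1.92 ± 0.25) and HLA-DMB (-1.84 ± 0.08) of 11 lower with PAN02 exosomes (median -0.19, random lists -0.33 to 0.37) and CTSS (1.31 ± 0.16) of 13 higher with BxPC-3 exosomes (median 0.32, random lists -0.23 to 0.17). Genes of alternative macrophage activation had SEPP1 (1.48 ± 0.46) and MAOA (1.27 ± 0.24) of 13 higher and IL1RN (-2.76 ± 0.60) lower in the first (median -0.19, random lists -0.40 to 0.44), and CCL13 (2.22 ± 0.13) and CCL18 (0.0922 and 0.252 CPM) of 17 higher in the second (median 0.15, random lists -0.26 to 0.22). Integrins and adhesion receptors had ITGA9 (0.257 and 1.61 CPM), ITGA1 (1.22 ± 0.15) and ITGA4 (1.12 ± 0.13) of 23 higher and ITGA2 (-1.75 ± 0.09) and CD44, barely past the 2-fold limit, lower with PAN02 exosomes (median 0.30, random lists -0.12 to 0.30, and -0.02 with total counts), against ITGA3 (-1.15 ± 0.06) of 26 lower with BxPC-3 exosomes (median -0.03, random lists -0.12 to 0.14). Of the S100 genes S100A10 (1.03 ± 0.12) of 9 was higher with PAN02 exosomes (median 0.20, random lists -0.29 to 0.42, and -0.12 with total counts). S100A9 (0.0860 and 0.214 CPM) and S100B, at 0 counts with PBS (up to 0.0184 CPM) and 0.126 CPM with BxPC-3 exosomes, were higher of 10 in the second (median -0.07, random lists -0.24 to 0.24).

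In the PAN02 comparison TF (0.112 and 0.246 CPM) of 8 hepatocyte genes was higher (median 0.27, random lists -0.43 to 0.48, and -0.04 with total counts), and of 8 endothelial genes ERG (0.0112 and 0.117 CPM, log2 ratio 2.47, counting interval 1.32 to 6.54, from 2 counts with normal pancreas exosomes) was higher and ESAM (-1.06 ± 0.13) lower (median -0.18, random lists -0.46 to 0.49, and 0.16 without the filter on counts). IL7R (27.8 and 5.81 CPM, log2 ratio -2.26 ± 0.15) and ZAP70 (0.240 and 0.0713 CPM) of 6 T and natural killer cell genes (median -0.49, random lists -0.54 to 0.58) and CD83 (1.36 and 0.253 CPM, log2 ratio -2.37 ± 0.31) of 5 dendritic cell genes (median -0.01, random lists -0.55 to 0.73) were lower, and BANK1 (0.106 and 0.266 CPM) and IGJ (0.268 and 0.590 CPM) of 5 B and plasma cell genes (median 0.42, random lists -0.81 to 0.81) were higher. FPR1 (0.797 and 0.350 CPM) of 4 neutrophil genes was lower (median -0.09). Of 4 pancreatic genes SPINK1 (0.112 and 0.259 CPM) was higher and CTRB1 (0.106 and 0.00648 CPM, log2 ratio -2.67, counting interval -9.41 to -1.38, from 1 count with PAN02 exosomes) lower (median -0.01). In the BxPC-3 comparison 0 of 10 hepatocyte genes (median -0.16, random lists -0.38 to 0.30), 0 of 3 T and natural killer cell genes (median -0.22), 0 of 4 neutrophil genes (median -0.00) and 0 of 1 pancreatic gene, GP2 (median -0.25), passed, while LAMP3 (1.64 ± 0.34) of 5 dendritic cell genes was higher (median 0.25, random lists -0.53 to 0.49) and IGJ (-1.39 ± 0.20) of 4 B and plasma cell genes lower (median -0.18). Replication histones, whose transcripts mostly lack poly(A) tails, had 6 of 13 lower and 0 higher with PAN02 exosomes (median -0.996, random lists -0.36 to 0.34) and 0 of 10 past the rule with BxPC-3 exosomes (median -0.03, random lists -0.29 to 0.23). ASNS was named after its value was seen, to complete a count. Of 40 ribosomal protein genes 0 passed in either comparison (median 0.21, random lists -0.00 to 0.30, and -0.11 with total counts, and median 0.12, random lists -0.07 to 0.14). The 13 mitochondrially encoded genes have no row in either table.

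The cell types that the transcripts point to differ from the label. That macrophage genes were left out of the counting altogether is argued against, since 30 of the 30 list genes had counts in at least 1 library, but only 19 and 17 had any in the libraries of the first table, and a partial loss was not tested. A mostly macrophage culture with few stellate cells is argued against, since the macrophage median reached at most 0.105% of the stellate median. The stellate list had the highest median of the cell type lists in 4 of 4 libraries, which is consistent with cultures mainly of stellate or fibroblast-like cells by day 14. Which of stellate cells, fibroblasts or smooth muscle cells these may be was not resolved. Whether the cells changed during culture or were of another kind from the start was not tested, since the series has no library from before treatment. In the stellate list 15 to 19 of 24 genes stood above 100 CPM, but LRAT stood at 0.173 to 0.201 CPM. DES stood at 0.0223 to 1.83 CPM and RELN at 0.552 to 2.16 CPM. In the same list PDGFRB stood at 149 to 840 CPM and HAND2 at 30.4 to 47.5 CPM. LRAT, RELN, PDGFRB and HAND2 were named after their values were seen.

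The lower chemokines and higher matrix genes of the PAN02 exosome library were weighed against 3 technical explanations. A larger share of counts in matrix and stellate genes (17.8% against 7.42%) lowers all other genes alike. With those genes out of the totals the chemokine median was -1.84 and the median of all other genes -0.15. Their removal moves both medians together and so decides nothing. The gap between the medians, which a common shift cannot make, argues against the share as the whole cause. GC content and transcript length are argued against by medians of -1.47 for chemokines and 1.02 for matrix genes after their trend was removed, both still outside random lists. A normal pancreas exosome library that stands apart stays open: with all 4 libraries on 1 scale it was the highest for 8 of the 11 lower chemokines, but the table and the pair of treatments are confounded. Medians of the 17 chemokines kept in both tables were 22.4 (normal pancreas exosomes), 3.29 (PAN02 exosomes), 1.76 (PBS) and 13.4 CPM (BxPC-3 exosomes). Under the same limit, the PAN02 exosome library was the highest for 21 of 30 matrix genes and 30 of 34 interferon-stimulated genes. Of 23 stellate cell and fibroblast genes it was the highest for 10 and the PBS library for 8. ACTA2, TAGLN and CNN1 were among the latter. ACTA2 stood at 241 (normal pancreas exosomes), 4402 (PAN02 exosomes), 5368 (PBS) and 2075 CPM (BxPC-3 exosomes). Matrix medians on that scale were 791 (normal pancreas exosomes), 1789 (PAN02 exosomes), 1169 (PBS) and 1294 CPM (BxPC-3 exosomes). A difference in RNA quality or selection stays open, for the interferon and stellate lists as well, and was not tested. The median of replication histones, -0.996, lay below random lists in this comparison only. Immediate early and dissociation stress genes, with a median of -0.31, also lay below them in this comparison only, and a difference in such stress was not tested. A difference between the 2 kinds of exosomes stays open as well.

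Of the 10 splits of the 6 columns of each table into 3 and 3, the real one gave the most genes, 7778 and 4708, and the highest of the others 0 and 0. The number of splits with as many genes was 1 in each table, and 10 splits are too few for a share under 0.05.

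In a principal component analysis of the 12 columns the first component, with 66.25% of the variance, separated the 2 tables, which differ in both treatments. On the second component, with 17.9%, normal pancreas exosome columns lay at -40.8 to -23.1 and PAN02 columns at 43.6 to 48.4, PBS columns at 0.534 to 8.82 and BxPC-3 exosome columns at -26.2 to -9.36.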
